A study of Homo sapiens with 2 samples.

How the data were processed

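Gene expression was measured with Affymetrix microarrays in PC-3 cells, a human prostate cancer cell line, in 2 samples. Per the labels' protocols, near-confluent cells were starved of serum overnight and then kept for 48 h in medium with 1% serum. The cells of 1 sample received recombinant human TGF-β1 at 5 ng/mL and those of the other its vehicle, a buffered albumin solution. Whether a sample was a single culture or a pool of cultures is not given in the sources used here. Total RNA was purified on columns and biotin-labelled cRNA was hybridised, per the labels' protocols. Each group has 1 array.

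The deposited values are intensity values on a linear scale, 1 signal per probe set and array, made by the authors with Microarray Analysis Suite (MAS5), per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The scaling target and the background settings are not given in the sources used here, and detection calls were not used here. The 2% trimmed mean over all probe sets was 250.1 on both arrays, so the values had been brought to a common mean before deposit. Such scaling sets the mean of each array to the same level and hides any change in total mRNA per cell. Scanner files were not used here. With 1 array per group, the number of arrays limits the precision.

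Each array gave signals for 22283 probe sets, of which 68 were control probe sets and were kept out of the gene comparison. Of the other 22215, the platform annotation used here gave 1 gene symbol for 19065 and several for 1043, and 2107 were unnamed here. Gene IDs were matched to a RefSeq gene table, in which 12 named probe sets had no match, and 0 symbols were changed. No gene was named from a probe set with several symbols. The arrays' files name no genome build, so no coordinates are given. A gene was represented by its named probe set with the highest mean log2 signal, which gave 11963 genes.

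The floor was the median of all non-control signals of both arrays pooled, 82.5. A signal under the floor was set to it before log2 was taken. A gene with 1 array under the floor therefore has only a bound, written as "at least" a fold, and a gene with both arrays under it was not counted as measured. The log2 ratio is that of the TGF-β array minus that of the vehicle array. No test was run and no p-value is given, because a group of 1 has no spread. A ratio was called at a fold of 2 or more. The only error that could be measured was technical, the standard deviation of log2 ratios between probe sets of the same gene, with a bootstrap interval from 1000 draws over genes. It covers differences between probes and not differences between cell samples.

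The gene lists were 22, fixed with the floor, the threshold and the alternatives before the data were examined. They cover canonical TGF-β targets, TGF-β and BMP pathway components, mesenchymal, epithelial, extracellular matrix, protease and inhibitor, integrin and focal adhesion, actin cytoskeleton, bone metastasis, inflammatory, interferon-stimulated, G1/S, G2/M, CDK inhibitor and apoptosis, hypoxia and glycolysis, cholesterol and fatty acid synthesis, unfolded protein response, prostate and androgen-regulated, neuroendocrine, blood cell, housekeeping and immediate early genes. For each list the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list was called outside the range of random lists when its percentile was under 2.5 or over 97.5. Each median also had a 95% bootstrap interval over its members, from 10000 draws, used to judge how far alternatives moved it. For lists with under 5 measured members the spread between probe sets was used instead. The percentile describes the 2 arrays and is no test of the treatment.

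The named genes follow a rule with these parts. The first takes the 10 genes with the largest ratio in each direction among those measured on both arrays, leaving out a gene with another measured probe set that went the other way. The next takes the 5 largest bounds in each direction among genes with 1 array under the floor. Another takes up to 4 members of each list with the largest ratios. PMEPA1, SMAD7, SKIL, PTHLH, IL11, CCN2, CXCR4, CDH1, VIM, FN1, MYC, CDKN1A and ID1 were always to be given where present. PTHLH had no probe set with that symbol alone in the annotation used here and is not analysed here. Some items that the rule also takes are not reported here. The last part takes the control probe sets of GAPDH and ACTB and the spiked bacterial controls.

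The alternatives were scaling to the median of measured probe sets, quantile normalization, a loess correction on mean log2 signal (span 0.3, 3 iterations), floors at the 25th and 75th percentiles, a pseudocount of 32 in place of the floor, the median over all probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, whose probes can match several transcripts, and thresholds of 1.5-fold and 3-fold. Scaling to the spiked controls, and quantile normalization together with the low floor, were added after seeing the data. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9.

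The scripts were tested on simulated data for the comparison of 1 TGF-β array with 1 vehicle array over 7024 genes. Of 100 genes planted at a log2 ratio of 1.25, 75 were called at 2-fold, and of 100 planted at 2.5, 89 were called. Of 6792 unchanged genes 0 were called. The simulated noise was normal and independent between probe sets, with the spread found between probe sets of a gene. In the real data 9 of 4968 probe sets differed by 1.22 or more from the mean of their gene's others. The 0 is therefore no rate of false calls for the real arrays. A list of 35 genes shifted by 0.25 lay at percentile 100 of random lists, and a list of 35 unchanged genes at percentile 79.3.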

Results

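The study compared gene expression in PC-3 cells exposed to TGF-β1 with that in PC-3 cells exposed to vehicle. PC-3 is an androgen-independent human line established from a bone metastasis of prostate cancer. TGF-β1 is a secreted growth factor, abundant in bone matrix, that signals through serine/threonine kinase receptors and SMAD transcription factors. The question was which transcripts differ after 48 h at 5 ng/mL. There was 1 array for TGF-β and 1 for vehicle, so no value below has a replicate error, and a difference between the arrays cannot be told apart from a difference between the 2 cell samples that is unrelated to TGF-β.

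The median signal of the non-control probe sets was 79.9 on the TGF-β array and 85.3 on the vehicle array, and the highest signals were 12509 and 11365. Of the 11963 named genes, 7097 reached the floor of 82.5 on at least 1 array. Among these, 6562 did so on both arrays, 168 only on the TGF-β array and 367 only on the vehicle array. The other 4866 genes were under the floor on both. Across the 10609 probe sets at or above the floor on both arrays, log2 signals correlated with a Pearson r of 0.982 and a Spearman rho of 0.973, a relation across probe sets, which are not independent replicates.

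RNA integrity was read from control probe sets at both ends of a transcript. The 3′ to 5′ signal ratio of GAPDH was 0.755 with TGF-β and 0.795 with vehicle, and that of ACTB was 1.03 and 1.00. The 17 spiked bacterial control probe sets at or above the floor were on average 1.10-fold brighter on the TGF-β array (log2 0.14 ± 0.18, SD over probe sets), and 13 of the 17 were brighter there. All 9 ribosomal RNA control probe sets were brighter on the TGF-β array and all were under the floor, with highest signals of 79.1 and 55.8.

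Genes of the extracellular matrix led the differences. COL6A3, a chain of the microfibrillar collagen VI, had a signal of 828 with TGF-β and 161 with vehicle, a 5.15-fold difference and the largest of any gene measured on both arrays. SERPINH1, the collagen chaperone of the endoplasmic reticulum, was 3.14-fold higher with TGF-β (261 against 83.0, just above the floor). COL4A2 and COL4A1, the basement membrane collagen IV chains, were 2.09-fold and 2.07-fold higher, and a second COL4A1 probe set had a log2 ratio of at least 0.35. CCN2, a matricellular protein and a classical TGF-β target, was 2.56-fold higher (486 against 190). The collagenase MMP1 went the other way and was 2.09-fold lower with TGF-β (297 against 620).

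At the 2-fold threshold, 14 genes were higher with TGF-β and 12 were lower, together 0.366% of the measured genes. At 1.5-fold, 121 were higher and 133 lower, and 96.4% of measured genes lay within 1.5-fold. All 14 higher genes were measured on both arrays, as were 10 of the 12 lower ones. Beyond the matrix genes, PKIA, an inhibitor of protein kinase A, was 2.70-fold higher, and PODXL, the sialomucin podocalyxin, was 2.61-fold higher. The serine protease inhibitor family members SERPINB7 and SERPINB5 were 2.48-fold and 2.06-fold higher. CDH1, the epithelial adhesion protein E-cadherin, was 2.34-fold higher (519 against 222), while its second probe set was under the floor on both arrays (76.4 and 63.2). DUSP6, a phosphatase of the kinase ERK, was 2.16-fold higher by its brightest probe set (2139 against 989), and its other probe sets were 1.19-fold and 1.32-fold higher. NPIPA1 was 2.57-fold higher but belongs to a family of near-identical copies and its probes can match several transcripts, so its identity is uncertain.

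**Figure D1:**
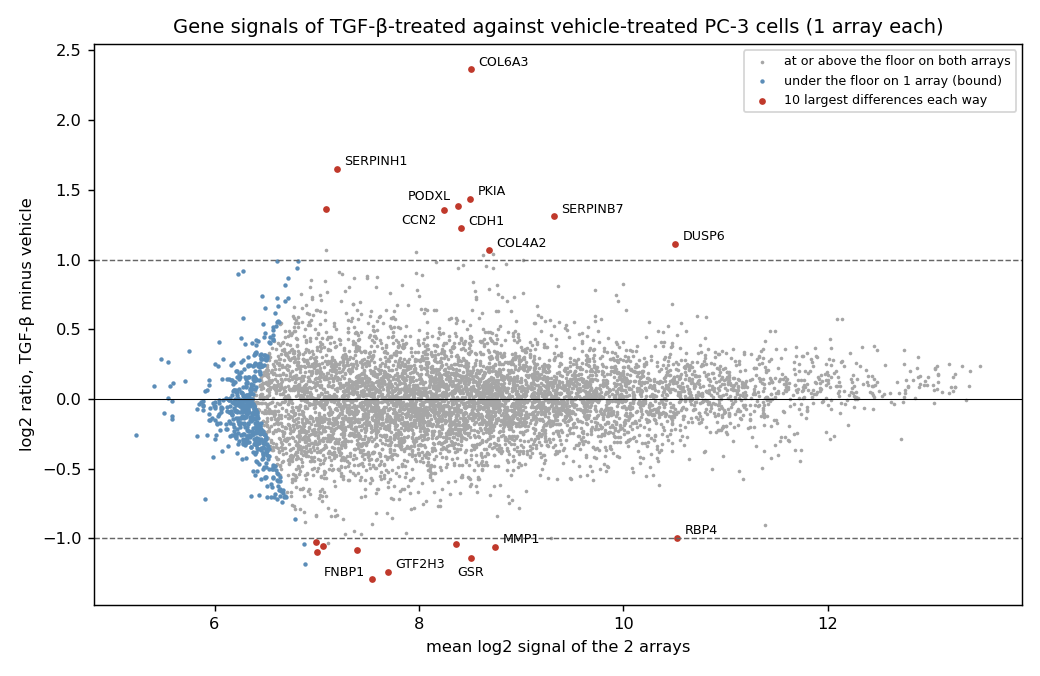
Log2 ratio (TGF-β minus vehicle) of each measured gene against its mean log2 signal on the 2 arrays, with dashed lines at 2-fold. Blue points have 1 array under the floor and show bounds. Red points are the 10 largest differences in each direction by the naming rule, with COL6A3 highest at 2.36. That rule takes genes measured on both arrays and leaves out those with another measured probe set in the other direction.

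Among lower genes, FNBP1, which encodes a formin-binding protein, showed the largest difference measured on both arrays (2.45-fold, 119 against 292). GSR, the glutathione reductase that keeps glutathione reduced, was 2.20-fold lower (245 against 540). AVEN, an apoptosis inhibitor, was 2.15-fold lower, and GLE1, an mRNA export factor, was 2.12-fold lower. ASCC1 and ARHGAP6 were 2.07-fold and 2.04-fold lower, with TGF-β signals of 92.6 and 88.9 near the floor. GTF2H3 and PPDPF were 2.36-fold and 2.05-fold lower. The values of GTF2H3, PPDPF, GLE1, ASCC1, ARHGAP6 and RBP4, and among the higher genes those of SERPINH1, SERPINB7 and CDH1, come from _x_at or _s_at probe sets, whose probes can match several transcripts. RBP4, the retinol carrier, had a high signal and fell short of the threshold at 1.998-fold lower (1045 against 2089).

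**Figure D2:**
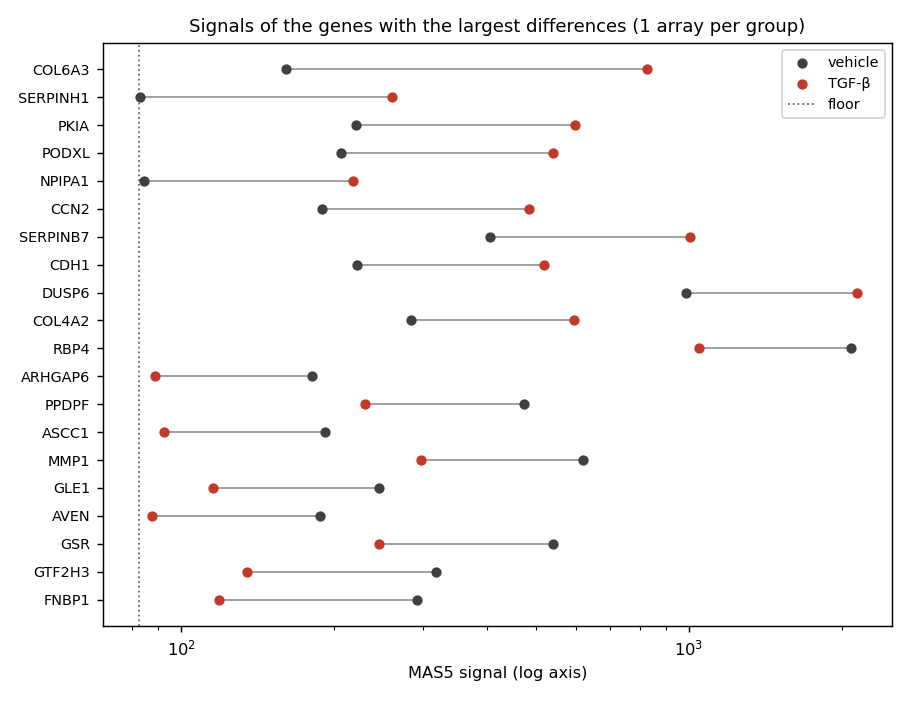
Signals on the TGF-β array (red) and the vehicle array (dark grey) for 10 genes in each direction, on a log axis. They have the largest differences by the naming rule, among genes measured on both arrays. The floor of 82.5 is a dotted line. SERPINH1 and NPIPA1 lie near the floor with vehicle, at 83.0 and 84.7, and AVEN lies near it with TGF-β, at 87.7.

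Some genes reached the floor on 1 array only. With TGF-β, MYBL2, a cell cycle transcription factor, was at least 1.98-fold higher, KRT7, a simple epithelial keratin, at least 1.89-fold higher, and CYP27A1, the sterol 27-hydroxylase, at least 1.87-fold higher. ZNF428 and ZNF175 were at least 1.99-fold and 1.92-fold higher. In the other direction, ACVR2B, an activin receptor, was at least 2.27-fold lower (74.2 against 187), and AXIN1, a scaffold of the β-catenin destruction complex, at least 2.05-fold lower. TRIM58, SFTPC and MINDY2 were at least 1.82-fold, 1.67-fold and 1.65-fold lower. The SFTPC value rests on 1 _s_at probe set (73.9 against 138), whose probes can match several transcripts. Its other probe sets were far under the floor on both arrays, the brightest at 6.61 with TGF-β and 8.24 with vehicle. Whether that value reflects SFTPC is therefore uncertain.

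The spread of log2 ratios between probe sets of the same gene was 0.228 (SD, 95% bootstrap interval 0.221 to 0.237, 2046 genes), and the spread between genes after taking it out was 0.145. This spread is technical and leaves out any difference between cell samples, so it does not show whether a 2-fold difference would recur. Across the 2046 genes the ratios of the brightest and of the other probe sets correlated with r = 0.299 (rho = 0.287), and 62.5% had the same sign. Of the 26 genes at 2-fold, 3 had another probe set measured on both arrays, and in 2 of them, COL4A2 and DUSP6, it had the same direction (66.7%, exact 95% interval 9.43 to 99.2%). The exception was SLC35D2, which the naming rule leaves out and which was named after its values were seen: 1 probe set was 2.04-fold lower and the other 1.00-fold. Of the 50 genes at 1.5-fold with another probe set, 37 had the same direction in all (74.0%, exact 95% interval 59.7 to 85.4%).

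**Figure D3:**
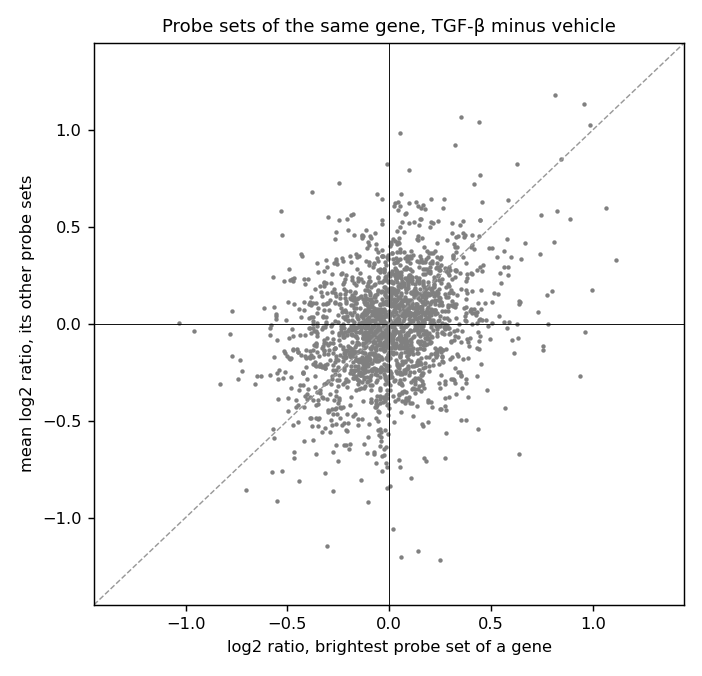
Log2 ratio (TGF-β minus vehicle) of the brightest probe set of each of 2046 genes against the mean of its other probe sets, both measured on both arrays. The dashed line marks equal ratios; the points scatter widely around it, with r = 0.299 across genes.

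The counts depend on the floor. With the floor at the 25th percentile 95 genes were higher and 199 lower, and with the floor at the 75th percentile 6 were higher and 1 was lower. Scaling to the spiked controls, which moved the median of all genes to −0.14, gave 8 higher and 22 lower genes. That scaling applies 1 factor to each array, so a list median between 0 and 0.14 turns below 0 by construction. The lists that turned under it are given below with the median relative to all genes, in which none of these lists turned. The bone metastasis median, 0.152 as reported, lay above 0.14, and its turn came with 17 measured genes in place of 16.

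Of the 22 gene lists, 8 lay outside the range of random lists, 4 above and 4 below. If lists and their genes varied independently, 1.1 lists would do so. The lists share members, and random lists do not keep genes that vary together. The 1.1 is therefore no chance level for these 2 arrays. The extracellular matrix genes stood farthest above random lists. Their 35 measured members had a median log2 ratio of 0.24 and a percentile of 100, with 25 above 0, 4 at 2-fold higher and 0 at 2-fold lower. The median was 0.16 after the loess correction and 0.10 with scaling to the spiked controls. FN1, fibronectin, was 1.18-fold higher (4951 against 4202), and its other 4 measured probe sets had log2 ratios of 0.28 to 0.40. The 24 measured canonical TGF-β targets had a median of 0.17 (percentile 99.9), with 15 above 0 and CCN2 alone at 2-fold. The bootstrap interval over members spanned 0 for the targets (−0.015 to 0.42), epithelial genes (−0.25 to 0.24) and proteases (−0.093 to 0.25). It also did for bone metastasis (−0.12 to 0.34), interferon-stimulated (−0.14 to 0.017) and unfolded protein response genes (−0.19 to 0.068). It did not for matrix (0.014 to 0.33) and immediate early genes (−0.33 to −0.015). SMURF2, a ubiquitin ligase that limits SMAD signalling, had a log2 ratio of 0.56, LTBP3, a latent TGF-β binding protein, 0.51, and TNC, the matrix protein tenascin-C, at least 0.52. The median of the targets was 0.42 without the _x_at and _s_at probe sets, where only 9 were measured, and 0.03 with scaling to the spiked controls.

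Several TGF-β targets named beforehand were too dim to measure. PMEPA1, a SMAD-binding membrane protein that limits TGF-β signalling, had signals of 42.1 with TGF-β and 2.79 with vehicle, both under the floor. With the floor at the 25th percentile, 20.7, it was at least 2.03-fold higher with TGF-β. SMAD7 (42.6 and 36.6) and SKIL (67.4 and 35.1), further inhibitors of the pathway, were also under the floor on both arrays. IL11, a cytokine that promotes bone resorption, was at least 1.09-fold lower with TGF-β (25.7 against 89.9). Its log2 ratio was −1.81 with the 25th percentile floor, which both of its signals reach. A second IL11 probe set also reached that floor on both arrays (29.5 with TGF-β and 34.6 with vehicle) and had only −0.23. CXCR4, the chemokine receptor, had signals of 130 and 120. CDKN1A had a log2 ratio of 0.15, MYC one of −0.06 and ID1 one of −0.00, each within the spread between probe sets.

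The 23 measured components of the TGF-β and BMP pathways had a median of −0.07, inside the range of random lists (percentile 10.4), with 17 of 23 below 0. Without the _x_at and _s_at probe sets 13 were measured, and their median of −0.20 lay below random lists (percentile 1.13). ACVR2B was the only member at 2-fold. The activin and inhibin subunits INHBA and INHBB had log2 ratios of −0.88 and −0.62, and the ligand TGFB3 one of −0.53.

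Among adhesion and cell shape genes, members differed in both directions. The 21 mesenchymal genes had a median of 0.03 (percentile 64.1), which turned to −0.10 with scaling to the spiked controls (0.04 relative to all genes) and to −0.00 after loess. None was at 2-fold. CDH2, the mesenchymal N-cadherin, had a log2 ratio of 0.84 and its second probe set one of 0.85. SNAI2, a repressor of epithelial genes, had 0.49, LOX −0.35 with a second probe set at 0.08, and S100A4 −0.24. VIM, vimentin, was bright on both arrays (7291 with TGF-β and 6823 with vehicle). The 21 epithelial genes had a median of −0.12 (percentile 1.67), below random lists, but a mean of 0.04, with CDH1 and KRT7 higher. PPL, a desmosomal plakin, had −0.58 and the epithelial transcription factor ELF3 −0.45, with a second probe set at −0.09 or less. The epithelial median was inside the range of random lists with the 25th percentile floor (percentile 12.2), without the _x_at and _s_at probe sets (6.13) and with scaling to the spiked controls (3.80).

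For integrins and focal adhesions (23 measured) the median was −0.05 (percentile 10.0). ITGB5, an integrin β chain for vitronectin, had a log2 ratio of 1.00, just under 2-fold, with a second probe set at 0.18 and another, which can match several transcripts, at 2.47 or more (458 against 78.3). NEDD9 had 0.44 with a second probe set at 1.04, FERMT1 0.45 with a second at 0.77, and ITGA2 −0.42. The 27 actin cytoskeleton genes had a median of 0.01 (percentile 48.2) and a mean of −0.05, and the median turned to −0.13 with scaling to the spiked controls (0.01 relative to all genes), to −0.01 with the 25th percentile floor and to −0.00 with the probe-set median. MYLK, TPM4 and MYH9 of the contractile apparatus had −0.67, −0.47 and −0.41, and the capping protein CAPG 0.42.

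**Figure D4:**
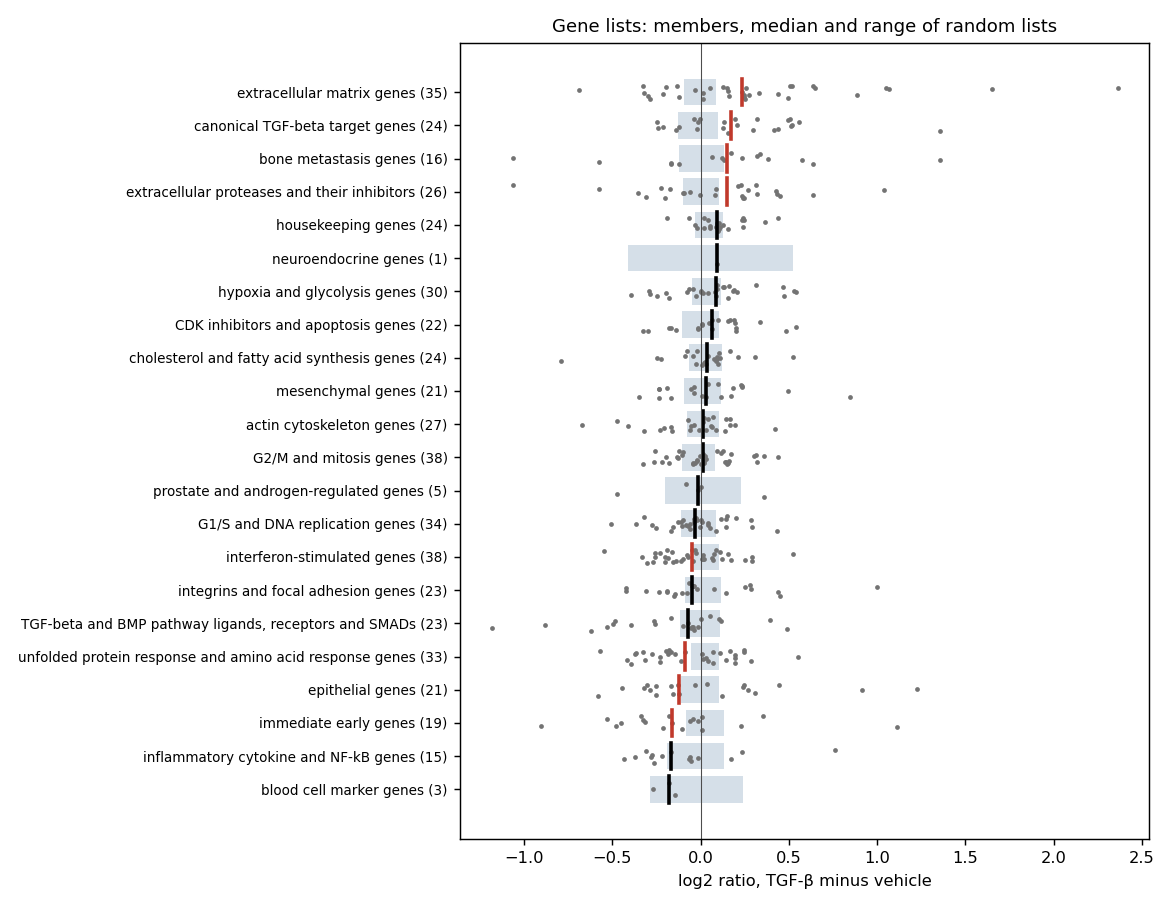
Log2 ratios (TGF-β minus vehicle) of the measured members of the 22 gene lists (grey points, number in parentheses), with the list median as a bar and the central 95% of the medians of 10000 matched random lists as a shaded band. Red bars mark the 8 lists outside the band, 4 above it, led by extracellular matrix genes at 0.24, and 4 below it.

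Among secreted factors of invasion and bone, the 26 extracellular proteases and inhibitors had a median of 0.15 (percentile 99.8), with SERPINB5 at 2-fold higher and MMP1 at 2-fold lower. The collagenase MMP13 had a log2 ratio of 0.64 and the protease ADAMTS1 one of −0.58. The 16 bone metastasis genes had a median of 0.15 (percentile 98.9), which turned to −0.01 with scaling to the spiked controls (0.13 relative to all genes). They share 4 measured genes, MMP1, MMP13, ADAMTS1 and PLAU, with the protease list, and CCN2 was their member at 2-fold higher. The protease percentile was inside the range of random lists under 4 alternatives and the bone metastasis percentile under 2. The protease median was 0.04 (percentile 78.8) with the probe-set median and 0.08 with the floor at the 25th or the 75th percentile. The 15 inflammatory cytokine and NF-κB genes had a median of −0.17 (percentile 4.82). It was −0.07 over 25 genes with the 25th percentile floor (percentile 48.1) and −0.07 over 5 genes with the 75th (percentile 29.2). CXCL6, a neutrophil chemokine, had 0.76, while RELB, TNFAIP3 and TNFAIP2 had −0.43, −0.37 and −0.31.

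Immediate early genes (19 measured) lay below random lists with a median of −0.16 (percentile 0.15), and 14 of 19 were below 0. DUSP5 and DUSP1, further phosphatases of MAP kinases, had log2 ratios of −0.90 and −0.53 and KLF4 −0.48, against 1.11 for DUSP6, the member at 2-fold. The list was inside the range of random lists with the 75th percentile floor (percentile 2.85). The 33 genes of the unfolded protein and amino acid responses had a median of −0.09 (percentile 0.245), with 17 below 0, which turned to 0.03 (percentile 53.5) without the _x_at and _s_at probe sets. TRIB3 had −0.57, WARS1 −0.42 with a second probe set at 0.07, DDIT3 −0.39 and CRELD2 0.55. The 38 interferon-stimulated genes had a median of −0.05 (percentile 1.90), with SP110 at −0.55 and its other probe sets from −0.67 to −0.02, IFIT2 at −0.33, IFIT3 at −0.30 and IFI6 at 0.52. Their percentile was inside the range of random lists under quantile normalization (2.92) and without the _x_at and _s_at probe sets (2.51).

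Growth and metabolism lists lay inside the range of random lists and had no member at 2-fold. The G1/S genes (34) had a median of −0.03 (percentile 33.3), which turned to 0.03 (percentile 69.0) without the _x_at and _s_at probe sets, with MCM7 at −0.51 and a second probe set at 0.02, E2F1 at −0.37 with a second probe set at 0.01 or more, CHAF1A at −0.32 and UNG at 0.43. The G2/M genes (38) had a median of 0.01 (percentile 68.3), which turned to −0.13 with scaling to the spiked controls (0.01 relative to all genes). TOP2A had 0.44 with a second probe set at 0.11, BIRC5 0.36 with other probe sets from −0.12 to 0.05, AURKB −0.33 and CENPE 0.32. With that same scaling the next 3 medians also turned: CDK inhibitors and apoptosis genes (22) from 0.06 (percentile 88.8) to −0.08, hypoxia and glycolysis genes (30) from 0.09 (percentile 88.7) to −0.06, and cholesterol and fatty acid synthesis genes (24) from 0.03 (percentile 55.8) to −0.11. Relative to all genes these 3 medians were 0.06, 0.08 and 0.03 with that scaling, at percentiles 84.6, 89.4 and 53.9. BNIP3, a mitophagy receptor, had 0.54 with a second probe set at 0.26, CASP8 0.48 with a second at −0.01, BAX at least 0.34 and GADD45B −0.32 with others at −0.43 and −0.34. The glycolytic PFKP, PFKFB3 and HK2 had 0.53, 0.47 and 0.46. The mevalonate enzyme MVD had −0.79, the desaturase FADS2 0.53, FASN −0.25, and ACLY 0.31 with other probe sets at −0.24 and −0.10.

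Lineage and control lists were small or near 0. Of the prostate and androgen-regulated genes 5 were measured, with a median of −0.01 (percentile 33.1) that was 0.01 with median scaling and −0.18 over 13 genes with the 25th percentile floor. They were TMPRSS2 at −0.47 with a second probe set at −0.13, HOXB13 at 0.36, ABCC4 at −0.08 and STEAP1 at −0.01, with NDRG1 as the other member. ENO2 was the single neuroendocrine gene measured, at 0.09 (percentile 66.1), which turned to −0.05 with scaling to the spiked controls (0.09 relative to all genes). With the 25th percentile floor 10 neuroendocrine genes were measured, with a median of −0.12 (percentile 50.6). The 3 measured blood cell markers, LCP1 at −0.27, HBB at most −0.18 and CD3D at most −0.14, had a median of −0.18 (percentile 13.1). A second HBB probe set went the other way, at 0.11 or more (88.7 against 63.1). The 24 housekeeping genes had a median of 0.09 (percentile 86.9), with 20 above 0, which was 0.02 after loess and turned to −0.05 with scaling to the spiked controls (0.09 relative to all genes). POLR2A had 0.44, SNRPD3 0.37, VCP 0.24, and PSMB2 0.25 with a second probe set at −1.22.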

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

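Scaling to the spiked controls, and quantile normalization with the low floor, were chosen after seeing the data, and the other alternatives before. The counts of higher and lower genes, 14 and 12, stayed within 1.5 times under median scaling, quantile normalization, loess, the pseudocount, the probe-set median and without _x_at and _s_at probe sets. They were 95 and 199 with the floor at the 25th percentile, 6 and 1 at the 75th, 8 and 22 with scaling to the spiked controls, 137 and 129 with quantile normalization and the low floor, 121 and 133 at 1.5-fold, and 2 and 0 at 3-fold. Of the 26 genes at 2-fold, 26 were also at 2-fold under median scaling, 22 under quantile normalization, 24 under loess, 26 with the low floor, 7 with the high floor, 13 with the pseudocount, 21 with the probe-set median, 15 without _x_at and _s_at probe sets and 20 with scaling to the spiked controls. A higher floor shrinks ratios of dim genes by construction. The share of 2-fold genes with the same direction in their other probe sets rested on few genes: it was 2 of 3 as reported, 4 of 5 with median scaling and 19 of 33 (57.6%) with the low floor. It was 100% under quantile normalization (2 genes), loess (3), the high floor (1), the pseudocount (1), without _x_at and _s_at probe sets (1) and with scaling to the spiked controls (2). The spread between probe sets was 0.323 with the low floor, 0.184 with the high floor and 0.201 with the pseudocount. Of 198 list medians under alternatives, 14 left the bootstrap interval of their list over its members. For lists with under 5 measured members the limit was 0.228 from the reported median. Another 2, of lists outside the range of random lists, turned in direction within that interval and were counted apart. The other 182 counted as the same. Scaling to the spiked controls moved the median of all genes to −0.14 and with it the medians of mesenchymal (−0.10), integrin (−0.19), actin (−0.13), inflammatory (−0.31), interferon-stimulated (−0.19), G1/S (−0.17), G2/M (−0.13), CDK inhibitor (−0.078), hypoxia (−0.056), cholesterol (−0.11), unfolded protein response (−0.24) and housekeeping genes (−0.046), and turned bone metastasis genes to −0.0091. It applies 1 factor to each array, and relative to all genes the bone metastasis median was 0.13, over 17 measured genes in place of 16. Without _x_at and _s_at probe sets the bone metastasis median was 0.39 over 9 genes. The unfolded protein response median turned to 0.032 over 20 genes. These are changes of members as well as of values, and the cause was not tested. The housekeeping median was 0.020 after loess, which removes a trend with signal. The percentiles of the matrix genes and of the TGF-β targets stayed outside the range of random lists under all 9 alternatives. Those of epithelial genes, proteases, bone metastasis, interferon-stimulated, unfolded protein response and immediate early genes did not under at least 1, and the TGF-β and BMP pathway genes, inside as reported, were outside without _x_at and _s_at probe sets (percentile 1.13). Of 874 values of 107 named genes, 827 stayed within 0.228 of the reported log2 ratio. The sign differed in 12 values of 9 genes (ACLY, BIRC5, CXCR4, E2F1, ENO2, ID1, PSMB2, STEAP1, VIM), none at 2-fold. No paired analysis was possible because each group has 1 array. Signal over background limits what can be read of the 4866 genes under the floor.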

Other observations

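The genes, the comparison and the tests in this part were chosen after the results were seen, except the loess test of the matrix genes and the test of the collagen-modifying list. Of the 2046 genes with 2 or more probe sets measured on both arrays, 6 had all probe sets at least 1.5-fold higher with TGF-β and 1 had all at least 1.5-fold lower. In 1000 shuffles of ratios among these probe sets the mean counts were 0.487 and 0.572, and the highest total in a shuffle was 6. The shuffles break the link between probe sets of a gene, which read the same RNA. The excess over them therefore shows agreement between probe sets and is no test of TGF-β. Beside COL4A2 and CDH2, the higher genes were ATP1B1, the β subunit of the sodium pump (1.94-fold and 2.20-fold), GALNT10, an enzyme that starts mucin-type O-glycosylation (1.98-fold and 2.03-fold), HES1, a Notch-regulated repressor (1.76-fold and 2.26-fold), and RCN2, a calcium-binding protein of the secretory pathway (1.55-fold and 1.77-fold). The lower gene was MERTK, a receptor tyrosine kinase for GAS6 (1.63-fold and 1.81-fold). Of the 4 cadherins on the lists that were measured, CDH1 and CDH2 had log2 ratios of 1.22 and 0.84, CDH3 one of at least 0.27 and CDH11, the brightest (1994 against 2244), one of −0.17.

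Other genes linked to ERK signalling, picked after their values were seen and not tested as a group, had these log2 ratios beside those of DUSP6 (1.11, 0.26 and 0.40 in its 3 probe sets). SPRY2, a feedback inhibitor, had −0.57 (589 against 876), ETV4 −0.53 (238 against 344) and DUSP5 −0.90 (1956 against 3655). SPRY4 had −0.08, and ETV5 had −0.34, −0.02 and 0.28 in its 3 probe sets. FGFR1, a receptor upstream of ERK, had probe sets that disagreed: the brightest had 0.06, 1 had −1.74 (109 against 365), 1 had −0.67 and 1 at least 0.16. The CDH1 ratio of 1.22 rests on 1 probe set, and 9 of 4968 probe sets of genes with several measured ones differed by as much or more from the mean of their gene's other probe sets, by up to 1.47. CDH1 is among the largest ratios of 7097 measured genes, so this small share cannot tell whether its ratio is such an error. Of 27 control probe sets for Bacillus transcripts, 18 were lower on the TGF-β array, with median signals of 3.15 against 6.92.

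Matrix genes were higher on the TGF-β array, with a median log2 ratio of 0.24. A difference between the arrays that depends on signal level is argued against as the whole cause. After the loess correction the list median was 0.16, against −0.004 for all measured genes. The fall from 0.24 leaves room for a part. The list's percentile of 99.95 after that correction adds little, because random lists were already matched on mean signal. Error of single probe sets may contribute: for the 16 matrix genes with another measured probe set, the other probe sets had a median of 0.09, at percentile 93.7 of random sets and inside their range of −0.16 to 0.12, while the brightest ones had 0.25, at percentile 100. Of these 16 genes, 11 had other probe sets above 0. A response to TGF-β, which the design names, and a difference between the 2 cell samples unrelated to it both stay open and cannot be told apart, since there was 1 array per group.

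With the floor at the 25th percentile, lower genes outnumbered higher ones by a ratio of 2.09. A difference between the arrays near background could be the source, and after quantile normalization with the same floor the ratio was 0.942, with 129 lower and 137 higher genes. That method gives both arrays the same distribution by construction, and 18 of the 27 Bacillus controls being lower is not far from an even split, so background and a wider lowering of dim transcripts cannot be told apart here.

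It was asked as a hypothesis whether genes that modify and export collagen share the difference of the matrix genes, from a list that holds none of the matrix list's genes. Its 21 measured members had a median of −0.02, at percentile 37.1 and inside the range of −0.13 to 0.11 of random lists, with 9 above 0 and 0 at 2-fold. Collagen-modifying genes that the matrix list holds were left out of it, among them SERPINH1 at 1.65, PLOD2 at 0.89 and PLOD1 at 0.49, with P4HA1 at 0.16, P4HA2 at −0.20 and LOXL1 at −0.30. By the rule set beforehand, a median of 0 or less meant no shared difference, and these 21 genes met it narrowly. Their median was close to the −0.007 of all measured genes and inside the range of random lists, which reaches 0.11. They showed no shared rise beyond that range, and whether they share a smaller one cannot be told. The result does not cover the members left out, for which the hypothesis stays open.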
